A study of Homo sapiens with 6 samples.

How the data were processed

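The series holds 6 RNA-seq libraries of MCF10AT1 cells, 3 of the CD24low, CD44high fraction and 3 of the CD24high, CD44-positive fraction of a fluorescence-activated sort. Per the labels' protocols, cells were grown in DMEM/F12 with horse serum, EGF, insulin, cholera toxin and hydrocortisone, RNA was extracted with Trizol, rRNA of the cytosol and of mitochondria was depleted, and strand-specific libraries were made with random hexamers. Groups and replicate numbers were taken from the sample labels. No label says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

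The deposited values are a non-negative signal per gene: gene counts that the authors divided by DESeq2 size factors, per the submitters' processing notes and the deposited table. Those notes also name STAR 2.5.2, R 3.5.0 and the genome build hg38. The read counter, its strand setting, the version of DESeq2 and the annotation release are not given in the sources used here. In each library the values were whole multiples of 1 step, so whole reads were recovered by dividing by that step; 100% of values were whole within 0.1 reads. Recovered totals ran from 16691162 to 27293177 reads per library, and 1 read was worth 0.83 to 1.46 normalized counts. The shallowest library, CD24high replicate 3, gives the least precise low counts. Floors for a count of 0 were set at 3 reads per library and cover counting error only, since PCR copies were not told from molecules.

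The table lists 58381 gene IDs, of which 58261 matched the GENCODE 29 annotation on hg38 without their version and 56933 with it; symbols and coordinates are from that annotation. No read was found for 27150 IDs. Some reads appear to have been counted at several genes: 87 tested genes in 34 groups had identical reads in all 6 libraries. Some of these, such as genes of the UGT1A cluster, overlap at one locus, where shared exons can give the same reads. In 16 of 16 second copies of pseudoautosomal genes the reads equalled those of the first copy, which points to multi-mapped reads. Families of near-identical genes, genes with pseudogene copies such as CD24, and overlapping or antisense genes are therefore uncertain. Between replicates of a group, counts differed by more than sampling noise in each pair, so every library was counted once.

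Computation used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The main test was limma with a mean-variance trend on log2 (normalized count + 1), two-sided, with group as the only term. It covered the 16047 genes with a mean of at least 10 normalized counts and used Benjamini-Hochberg adjustment with a threshold of 0.05. The pseudocount understates the change of low genes. DESeq2, with its own size factors, and edgeR's quasi-likelihood test, with TMM factors, were run on the recovered reads of the same genes. The ratio of RUNX2 to RUNX1 was tested with an exact permutation test. Before the data were examined, the groups, the main test, 29 gene lists, the rule for named genes and 19 alternative settings were fixed.

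Camera was run with a preset correlation of 0.01 on the 26 lists with at least 5 tested members, and again with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way, gave a smallest adjusted p of 0.22 over the lists. Members of each list were counted by limma's p adjusted over all genes tested and adjusted over the list alone. A list's direction in camera and its median had the same sign in each of the 10 lists that passed.

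The rule for named genes took 10 fixed genes, then up to 12 genes per direction past limma's adjusted p with a mean of at least 100 and groups that do not overlap, then up to 2 members per list past that p or else the 1 with the smallest p. The second part gave 0 genes and the third 29. After the values had been seen, up to 3 members per list past the test over the list alone were added (37), and the rule for 12 genes per direction was applied with DESeq2's adjusted p. Genes named outside this rule, namely CD24P4, MT-RNR1, MT-CO1, WNT7A, WNT7B, COL1A2, COL3A1 and LUM in the results and the members of gene families in the closing section, were chosen after their values were seen. Some genes that the rule took are not reported here.

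The test was tried on simulated counts for the comparison of CD24low with CD24high, with 200 of 16047 genes changed and means, spreads and library sizes from the real libraries, each gene drawn on its own. With a fold of 2, limma recovered 54%, edgeR 53.5% and DESeq2 65% of the changed genes, with 9, 8 and 21 false calls. With a fold of 4 the shares were 96%, 96.5% and 96.5%, with 12, 12 and 28 false calls. The simulation holds no shift shared by the genes of a library, so these shares do not give the power in the real data. The alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, total scaling, quantile normalization, upper quartile centring, the replicate number as a block, no mean-variance trend, both count tools, edgeR with the block, each library left out, and an estimated correlation. Added after seeing the data were the split by rRNA share as a covariate, protein-coding genes alone, and leaving out both libraries numbered 3.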

Results

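RNA was measured in MCF10AT1 cells, a human breast epithelial line grown from a mouse xenograft lesion of immortal MCF10A cells that carried activated HRAS. Cells were sorted on the surface proteins CD24 and CD44 into a CD24low, CD44high fraction and a CD24high, CD44-positive fraction. The submitters' column descriptions call the first fraction CSC and the second Bulk, which leaves open whether the second was a gated fraction or all remaining cells; the fractions are named here by the CD24 level in their titles. Each fraction had 3 libraries of total RNA depleted of ribosomal RNA (rRNA). The series title names RUNX transcription factors and breast cancer stem cells, so the comparison asks how RUNX genes and other programs differ between the fractions. Recovered reads came to 27293177, 23548052 and 16691162 in CD24high replicates 1, 2 and 3, and to 26988295, 25173976 and 24421025 in CD24low replicates 1, 2 and 3. Differences are CD24low minus CD24high on the scale of log2 (normalized count + 1), and means are given ± SD with n = 3 libraries per group.

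Reads of rRNA took unequal shares of the libraries. Genes of rRNA type took 1.30%, 2.27% and 10.2% of the reads in CD24high replicates 1, 2 and 3, and 7.15%, 7.07% and 1.97% in CD24low replicates 1, 2 and 3. The ranges of the groups overlapped, but the high shares fell in 1 CD24high and 2 CD24low libraries. MT-RNR1, a mitochondrial rRNA, differed 88.7-fold between its highest and lowest library, while the mitochondrial mRNA MT-CO1 differed 2.23-fold. Values are therefore also given within libraries of similar rRNA share: CD24low replicate 3 against CD24high replicates 1 and 2 (low share), and CD24low replicates 1 and 2 against CD24high replicate 3 (high share). Each of these has 1 library on a side, CD24low replicate 3 or CD24high replicate 3, so neither was tested. On the first principal component CD24low replicate 3 lay between the other CD24low libraries and the CD24high libraries. A gap between low-share and high-share values can therefore come from these single libraries and cannot be assigned to rRNA share.

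**Figure D1:**
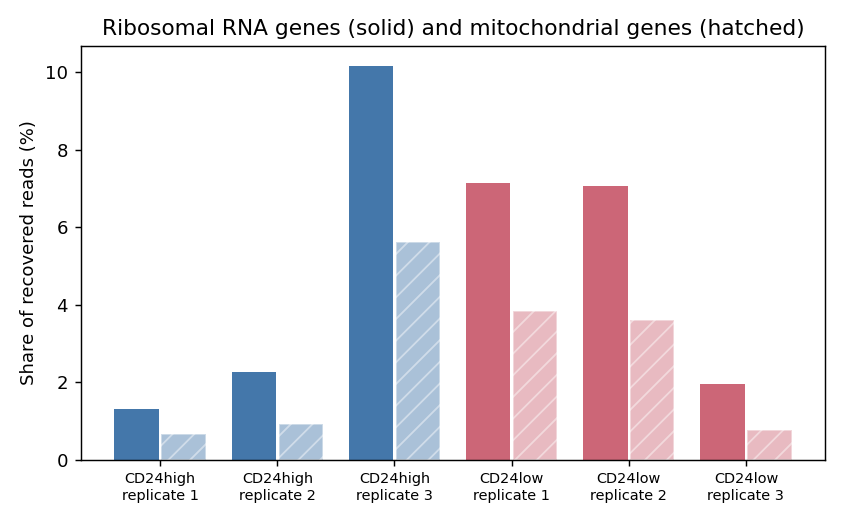
Percent of recovered reads (vertical axis) in genes of rRNA type (solid bars) and in mitochondrial genes (hatched bars) in each of the 6 libraries (horizontal axis). The rRNA share was 10.2% in CD24high replicate 3 and 7.15% and 7.07% in CD24low replicates 1 and 2, against at most 2.27% in the other libraries.

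The transcript of the first sorting marker followed the sort, and that of the second differed little. CD24 (ENSG00000272398.5, chromosome 6, 106969831 to 106975627, minus strand, hg38), a mucin-like surface protein, had 4018 ± 1681 normalized counts in CD24high and 762 ± 542 in CD24low cells, a log2 difference of -2.55 (SE 0.46). Every CD24low library lay below every CD24high library. Limma's adjusted p over all genes was 0.084 and over the luminal list alone 0.0041; DESeq2's adjusted p was 0.027. Within libraries of low rRNA share the difference was -1.16, and within those of high share -3.69. CD24P4, a processed copy of CD24, had 54.3 to 130 normalized counts in the CD24high libraries and 8.60 to 31.3 in the CD24low libraries, so the count of CD24 is uncertain by what the copies shared. CD44 (ENSG00000026508.18, chromosome 11, 35138870 to 35232402, plus strand), the hyaluronan receptor, had 8475 ± 562 and 7547 ± 716 normalized counts, a difference of -0.17 (SE 0.12, limma adjusted p = 0.56). With 1 library left out the CD44 difference ran from -0.24 (without CD24low replicate 1) to -0.10 (without CD24low replicate 3).

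Of the RUNX genes, RUNX2 rose in CD24low cells and the others did not pass the test. RUNX2 (ENSG00000124813.21, chromosome 6, 45328157 to 45664349, plus strand), the regulator of bone formation, had 33.0 ± 4.20 normalized counts in CD24high and 127 ± 49.2 in CD24low cells, a 3.61-fold difference (log2 1.85, SE 0.28). Its limma adjusted p was 0.00065 over the RUNX list alone and 0.068 over all genes, and DESeq2's was 1.2e-05. Within libraries of low and of high rRNA share RUNX2 differed by 1.31 and 2.25. RUNX1 (ENSG00000159216.18, chromosome 21, 34787801 to 36004667, minus strand), the main RUNX gene of these cells by count, had 1406 ± 400 and 1062 ± 115 normalized counts. Its difference of -0.37 (SE 0.18) had a limma adjusted p of 0.41 over all genes and 0.21 over the list alone, and it was -0.02 within libraries of low rRNA share and -0.88 within those of high share. With 1 library left out it ranged from -0.53 (without CD24high replicate 2) to -0.15 (without CD24high replicate 3). CBFB, the shared binding partner of RUNX proteins (chromosome 16, 67029116 to 67101058), had 1587 ± 327 and 1410 ± 133 normalized counts (-0.16, SE 0.15, limma adjusted p = 0.70). RUNX3 had 0 reads in all 6 libraries, which allows up to 2.49 to 4.38 normalized counts depending on the library, for counting error alone. The log2 ratio of RUNX2 to RUNX1 within a library was -5.34 ± 0.56 in CD24high and -3.11 ± 0.69 in CD24low cells. The groups did not overlap; the difference of 2.23 had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. In the list of RUNX genes and partners, 1 of 9 tested genes rose with adjustment over the list alone and 0 over all genes (1 with DESeq2; camera adjusted p = 0.97); over the list alone the count was 2 with DESeq2 and 3 with the replicate block in limma. Of 5 tested skeletal RUNX2 targets, genes that RUNX2 drives in bone, 0 passed over the list alone (median 0.28, camera adjusted p = 0.064), and 1 did without CD24low replicate 3. That list passed camera without CD24low replicate 1 (median 0.72, adjusted p = 0.017), without CD24low replicate 3 (adjusted p = 0.041), with total scaling (0.046) and without limma's trend (0.025), but its median was 0.11 without CD24low replicate 2 (adjusted p = 0.38) and 0.15 with no filter (0.77). With an estimated correlation, camera's adjusted p for that list was 0.47 in the main fit. BGLAP, encoding osteocalcin, had the smallest p of its 5 tested genes, with 11.5 ± 1.64 and 21.3 ± 2.44 normalized counts.

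**Figure D2:**
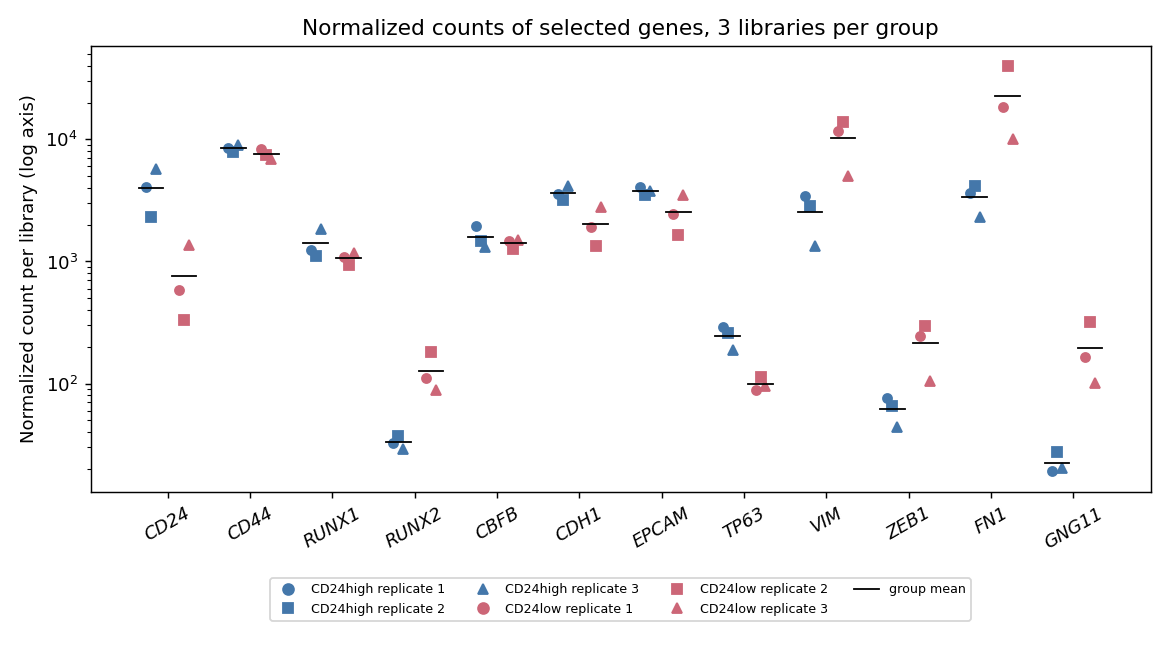
Normalized counts (vertical axis, log scale) of 12 genes in each library; colour gives the sorted group, the symbol gives the replicate, and black lines are group means of 3 libraries. Means of CD24 were 4018 in CD24high and 762 in CD24low cells, those of RUNX2 33.0 and 127, and those of VIM 2546 and 10192.

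Across the transcriptome, no gene passed limma's adjusted threshold in the main test, and DESeq2 called genes in either direction. Among genes called by DESeq2 with a mean of at least 100 normalized counts and groups that did not overlap, those with the largest positive differences included SRGN, the core protein of a secretory granule proteoglycan (log2 difference 3.82), TFPI, an inhibitor of the coagulation pathway (3.65), WNT5A (3.59) and FKBP10, a collagen chaperone (3.40). PCDH9, SNED1, ABCA6, GNG11, MAOA, ZEB2 and PLA2R1 followed, with differences from 3.24 to 2.73. Under the same limits, the largest negative differences were those of CD24, GJA5, which encodes the gap junction protein connexin 40 (-2.18), FST, the activin antagonist follistatin (-1.86), and the kallikrein protease KLK5 (-1.48). CLDN1, ABCA12, TP63, GDPD3, MIR205HG, ITGB6, TSPAN1 and EPN3 followed, with differences from -1.48 to -1.20. FST had 326 ± 107 and 87.7 ± 18.4 normalized counts, with a DESeq2 adjusted p of 5.9e-09 and a limma adjusted p of 0.068. With limma, 0 of 16047 genes passed an adjusted p of 0.05. The smallest adjusted p was 0.068, and 100 genes lay below 0.1. At an unadjusted p below 0.05 there were 2164 genes, where chance gives 802 on average. Genes can move together, so a count far from 802 can arise without a group difference. Other splits of the 6 libraries into 3 and 3 gave 114 to 1327 genes. The count below 0.1 was 719 without CD24low replicate 3, 5 without CD24low replicate 2 and 0 without any other library, and the unadjusted count fell to 1387 without CD24low replicate 2. DESeq2 on the recovered reads called 402 genes, 218 higher and 184 lower, and edgeR's quasi-likelihood test called 0, with 2263 at an unadjusted p below 0.05. With the replicate number as a block, limma called 716 genes, 347 higher and 369 lower, and edgeR called 705. No label says that a shared number marks one culture. The groups did not overlap for 3127 genes, 19.5% of those tested, where chance gives 10% on average, with a spread that was not measured. Without CD24low replicate 3, limma called 366 genes, 181 higher and 185 lower; on the first principal component that library lay at 3.83, against 22.9 and 55.0 for the other CD24low libraries and -34.2 to -15.9 for the CD24high libraries.

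Among gene lists fixed beforehand, 82 of 446 tested list genes passed limma's test with adjustment over the list alone, and 0 with adjustment over all genes. Counts of list genes that passed are out of the tested members, and list genes below the filter are left out of them. Of 26 lists tested with camera, 10 passed with a preset correlation of 0.01. With an estimated correlation 0 of them passed, and those p-values are given beside each list. Camera calls under other settings, including those of lists outside the 10, used the preset correlation too and were not repeated with an estimated one. The count of 82 was 48 without CD24high replicate 3, 46 without CD24low replicate 2 and 46 with the rRNA split as a covariate. It was 129 with the replicate block in limma and in edgeR, 117 without CD24low replicate 3, 109 without both libraries numbered 3, 108 with DESeq2 and 105 of 518 with no filter. Without limma's mean-variance trend it was 40, with 0 junction, 0 desmosome and envelope and 0 p53 genes, 5 basal genes, 2 TGF-beta genes and 0 YAP-TAZ genes among them.

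**Figure D3:**
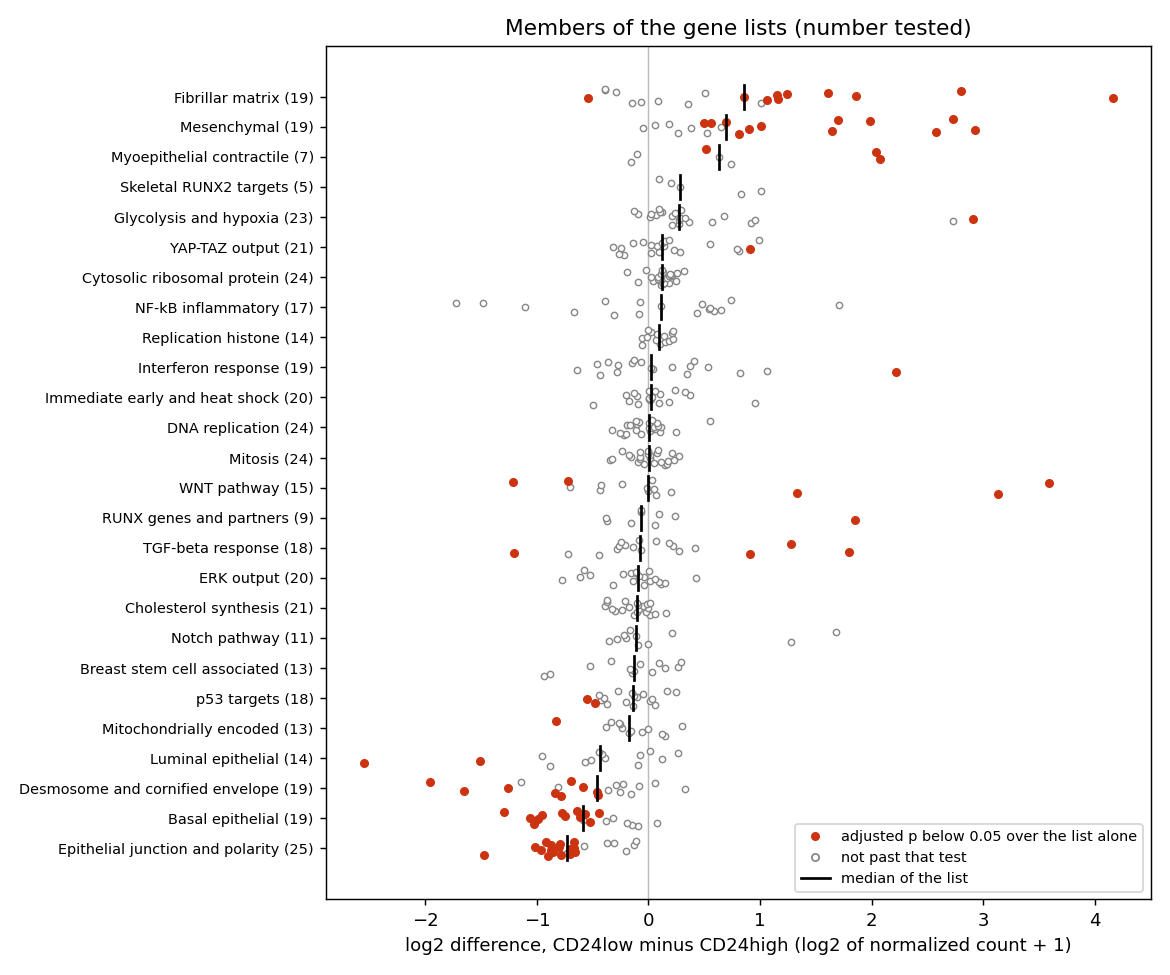
Log2 difference, CD24low minus CD24high (horizontal axis), of each tested member of 26 gene lists (vertical axis, with the number tested); filled points passed limma's test with adjustment over the list alone and black ticks are list medians. The medians ran from -0.73 for the epithelial junction list to 0.85 for the fibrillar matrix list.

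Most tested genes of epithelial junctions and polarity fell in CD24low cells. Of 25 tested, 18 fell, 0 rose and 7 did not pass over the list alone (0 over all genes, and 6 lower with DESeq2), with a median of -0.73. CDH1, which encodes E-cadherin (chromosome 16, 68737225 to 68835548), had 3616 ± 496 and 2014 ± 747 normalized counts (-0.90, SE 0.23, limma adjusted p over the list alone 0.016). EPCAM, an epithelial adhesion molecule (chromosome 2, 47345158 to 47387601), had 3801 ± 278 and 2519 ± 920 (-0.66, SE 0.23, adjusted p over the list alone 0.025); its difference was -0.38 without CD24low replicate 2, and -0.13 and -0.92 within libraries of low and of high rRNA share. The tight junction genes CLDN1 (-1.48) and OCLN (-1.01) and GRHL1, an epithelial transcription factor (-0.96), also fell. Within libraries of low rRNA share CLDN1, OCLN and GRHL1 differed by -0.55, 0.0095 and -0.26, and within those of high share by -2.25, -1.92 and -1.54. The groups overlapped for OCLN. Camera's adjusted p was 9.7e-14, and the adjusted p was 0.46 with an estimated correlation. The median was -0.06 within libraries of low rRNA share and -1.27 within those of high share. The count of 18 was 0 without CD24high replicate 3, 2 without CD24low replicate 1, 8 without CD24low replicate 2 and 2 with the rRNA split as a covariate.

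Most tested basal keratinocyte genes fell, and few luminal genes did. Of 19 tested basal genes, 12 fell, 0 rose and 7 did not pass over the list alone (0 over all genes, 7 lower with DESeq2), with a median of -0.59. TP63, the master regulator of basal epithelium (chromosome 3, 189631416 to 189897279), had 246 ± 51.6 and 98.9 ± 13.2 normalized counts (-1.29, SE 0.20, limma adjusted p over the list alone 0.0016), and it differed by -1.52 and -0.92 within libraries of low and of high rRNA share. COL17A1, a hemidesmosome collagen, had 6024 ± 547 and 3052 ± 902 (-1.02, SE 0.20), and KRT17, a basal keratin whose reads can be shared with near-identical copies, fell by 1.06. Camera's adjusted p for the basal list was 1.6e-10, and the adjusted p was 0.46 with an estimated correlation; its medians within low and high rRNA share were -0.33 and -0.62. The count of 12 was 7 without CD24high replicate 1. Of 14 tested luminal genes, 2 fell and 12 did not pass over the list alone (0 over all genes, 1 lower with DESeq2): CD24, which was used for the sort, and ESR1, the estrogen receptor, with 35.0 ± 4.41 and 11.9 ± 3.56 normalized counts (-1.51). The luminal median was -0.43 (camera adjusted p = 0.0027; adjusted p = 0.47 with an estimated correlation), -0.42 without CD24, but 0.19 within libraries of low rRNA share and -1.14 within those of high share. The luminal count of 2 was 4 without CD24high replicate 3, where the camera call was lost, and 8 without CD24low replicate 3 or with the replicate block. The luminal median was -0.27 without CD24high replicate 3, -0.25 without CD24low replicate 2 and -0.71 without CD24low replicate 3.

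Genes of desmosomes and the cornified envelope, the cross-linked shell of differentiating keratinocytes, had a median of -0.46. Of 19 tested, 9 fell, 0 rose and 10 did not pass over the list alone (0 over all genes, 5 lower with DESeq2). PERP, a desmosome protein, had 5179 ± 574 and 3458 ± 395 normalized counts (-0.58, SE 0.13, limma adjusted p over the list alone 0.018). The envelope genes SPRR1B (-1.96) and IVL (-1.65) and the keratin KRT16 (-1.26) fell too, from 21.3 ± 20.8, 88.9 ± 53.3 and 667 ± 402 normalized counts in CD24high cells. Camera's adjusted p was 7.6e-07, and the adjusted p was 0.46 with an estimated correlation. The median was -0.11 within libraries of low rRNA share and -0.70 within those of high share. The count of 9 was 14 without CD24high replicate 1, 1 without CD24high replicate 3, 0 without either CD24low replicate 1 or CD24low replicate 2, and 1 with the rRNA split as a covariate. Without CD24high replicate 3 the median was -0.26, and SPRR1B and KRT16 differed by -1.23 and -0.80.

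Most tested mesenchymal genes rose in CD24low cells. Of 19 tested, 12 rose, 0 fell and 7 did not pass over the list alone (0 over all genes, 8 higher with DESeq2), with a median of 0.69. VIM, the intermediate filament protein vimentin (chromosome 10, 17228259 to 17237593), had 2546 ± 1091 and 10192 ± 4627 normalized counts (1.98, SE 0.41, limma adjusted p over the list alone 0.0035). FN1, which encodes fibronectin, had 3367 ± 953 and 22745 ± 15326 (2.57, SE 0.42, adjusted p over the list alone 0.00077). The transcriptional repressors ZEB1 (chromosome 10, 31318495 to 31529814; 61.8 ± 16.5 and 217 ± 100, difference 1.70) and ZEB2 (54.8 ± 20.7 and 392 ± 233, difference 2.73) and the G protein subunit gene GNG11 (22.4 ± 4.61 and 195 ± 113, difference 2.92) rose too. Camera's adjusted p was 5.6e-11, and the adjusted p was 0.46 with an estimated correlation. The median was 0.33 within libraries of low rRNA share and 1.41 within those of high share. The count of 12 was 6 without CD24high replicate 3 and 7 without CD24low replicate 2.

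Part of the fibrillar matrix and contractile genes rose in CD24low cells. Of 19 tested matrix genes, 9 rose, 1 fell and 9 did not pass over the list alone (0 over all genes; 5 higher and 1 lower with DESeq2), with a median of 0.85. POSTN, the matrix protein periostin, had 7.15 ± 4.35 and 50.5 ± 8.5 normalized counts (2.80, SE 0.43), DCN, the proteoglycan decorin, had 160 ± 158 and 1845 ± 1612 (4.16, SE 1.05), and FBN1, encoding fibrillin, rose by 1.86. FAP, a protease of activated fibroblasts, fell (965 ± 164 and 660 ± 71.8, difference -0.54). Camera's adjusted p was 0.00023, and the adjusted p was 0.46 with an estimated correlation; the medians within low and high rRNA share were 0.33 and 0.64. The matrix median was 0.50 without CD24high replicate 1 and 0.53 without CD24low replicate 2, and DCN differed by 2.73 without CD24high replicate 3. Of 7 tested myoepithelial contractile genes, 3 rose, 0 fell and 4 did not pass over the list alone (0 over all genes, 2 higher with DESeq2): TAGLN, an actin-binding protein (2.04), MYL9, a myosin light chain (2.07), and TPM2, a tropomyosin (0.51). The contractile median was 0.63 (camera adjusted p = 0.0052; adjusted p = 0.47 with an estimated correlation), 0.18 and 0.78 within low and high rRNA share, and the count of 3 was 1 without CD24low replicate 2, where the median was 0.38, and 5 without CD24low replicate 3.

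Glycolysis, p53 and ribosomal protein genes passed the set test with few members past limma's main test. ENO2, a glycolytic enolase, rose (8.23 ± 3.84 and 79.6 ± 63.8 normalized counts, difference 2.91) as the 1 of 23 tested glycolysis and hypoxia genes past the test over the list alone; the median was 0.27 (camera adjusted p = 3.4e-05; adjusted p = 0.46 with an estimated correlation), 0.08 and 0.38 within low and high rRNA share. That count was 2 without CD24high replicate 2 and 3 without CD24low replicate 1, and over the list alone it was 8 with DESeq2, 5 with the replicate block in limma and 6 with it in edgeR. Of 18 tested p53 targets, 2 fell and 16 did not pass: MDM2, the ubiquitin ligase that degrades p53 (5236 ± 678 and 3569 ± 341, -0.55), and CDKN1A, the cell cycle inhibitor p21 (4061 ± 512 and 2902 ± 346, -0.48). The p53 median was -0.14 (camera adjusted p = 0.0084; adjusted p = 0.47 with an estimated correlation), -0.10 and -0.23 within low and high rRNA share. The count of 2 was 0 without CD24high replicate 1, CD24high replicate 3, CD24low replicate 1 or CD24low replicate 2, and 0 with the rRNA split as a covariate, but 3 with DESeq2 over the list alone and 4 with the replicate block. The camera call for that list was lost without CD24high replicate 3 or CD24low replicate 1. Of 24 tested cytosolic ribosomal protein genes 0 passed over the list alone, with a median of 0.12 (camera adjusted p = 0.0058; adjusted p = 0.89 with an estimated correlation) and 0.19 and 0.18 within low and high rRNA share. That camera call was lost without CD24high replicate 3 (median 0.05) and without CD24low replicate 3 (0.06). It was also lost in edgeR with the replicate block (camera adjusted p = 0.072) and without both libraries numbered 3 (0.997). With the rRNA split as a covariate the median was 0.20. Over all genes, limma called 0 members of these 3 lists, and DESeq2 called ENO2 and the 2 p53 targets.

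The WNT, TGF-beta and YAP-TAZ lists did not pass camera in the main test, though single members passed over the list alone. In the WNT pathway, WNT5A, a ligand of non-canonical WNT signalling (36.0 ± 25.5 and 436 ± 335 normalized counts, difference 3.59, SE 0.65), the secreted protein gene DKK3 (3.13) and the receptor gene FZD2 (1.33) rose, while the ligands WNT7A and WNT7B fell; 10 of 15 did not pass (median -0.0034, camera adjusted p = 0.97). Among TGF-beta genes, LTBP1, which holds latent TGF-beta in the matrix (1.79), TGFB1, the ligand itself (1.28), and CTGF, a matrix-associated growth factor (0.91), rose, and ITGB6, an epithelial integrin that activates the ligand, fell (2872 ± 541 and 1279 ± 435, difference -1.21); 14 of 18 did not pass (median -0.08, camera adjusted p = 0.97; -0.17 to 0.03 with 1 library left out). CTGF was also the 1 of 21 tested YAP-TAZ genes that rose (median 0.12, camera adjusted p = 0.11), but that list passed camera without CD24high replicate 1 (adjusted p = 0.024), CD24low replicate 2 (0.037) or CD24low replicate 3 (0.0055), without both libraries numbered 3 (median 0.27, adjusted p = 0.0038) and with no filter (0.018). Its median was 0.04 without CD24high replicate 2 (adjusted p = 0.74), 0.02 without CD24low replicate 1 (0.78) and 0.06 with the rRNA split as a covariate (0.41). With an estimated correlation, camera's adjusted p for the YAP-TAZ list was 0.96 in the main fit. Over all genes, limma called 0 members of these lists; DESeq2 called 3 higher and 1 lower in the WNT list, 3 higher and 1 lower in the TGF-beta list and 3 higher in the YAP-TAZ list. The WNT count of 5 was 3 without CD24high replicate 1 or CD24high replicate 2 and 1 without CD24low replicate 2. The TGF-beta count of 4 was 2 without CD24high replicate 2, and the YAP-TAZ count was 4 without CD24low replicate 3, 0 without any other library and 5 with the replicate block in limma.

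Stem cell, Notch and ERK lists had no member past the main test over the list alone. Of 24 breast stem cell genes 13 were tested and 11 lay below the filter. Of those tested 0 passed (median -0.13, camera adjusted p = 0.26). Their median ran from -0.19 without CD24high replicate 2 to -0.08 without CD24high replicate 1. The smallest p was that of ITGA6, a laminin receptor subunit (20059 ± 4455 and 13816 ± 2166, difference -0.53). Of 16 Notch genes 11 were tested and 0 passed (median -0.12, camera adjusted p = 0.93). The Notch median ran from -0.23 without CD24high replicate 1 to 0.03 without CD24high replicate 3. NOTCH3 had 48.1 ± 37.8 and 159 ± 125 normalized counts (1.68, SE 0.63). Its difference ran from 1.08 without CD24low replicate 2 to 2.28 without CD24high replicate 3. Of 20 ERK output genes 0 passed (median -0.10, camera adjusted p = 0.084), with EREG, an EGF receptor ligand, at -0.78 (SE 0.23; -0.58 without CD24low replicate 2). The ERK list passed camera without CD24high replicate 1 (adjusted p = 0.040), CD24low replicate 1 (0.033) or CD24low replicate 2 (0.027). It also passed with no filter (0.038) and with the rRNA split as a covariate (0.021). Its median was -0.06 without CD24low replicate 3 (0.33) and -0.16 without CD24high replicate 2 (0.20), and it passed in neither. With an estimated correlation, camera's adjusted p for the ERK list was 0.46 in the main fit. The counts of 0 were by limma's main test. Over the list alone, DESeq2 called 1 stem cell, 0 Notch and 4 ERK genes, the replicate block in limma 3, 2 and 5, and the fit with no filter 1, 0 and 2; DESeq2 over all genes called 0 in each list. Without CD24high replicate 3, 1 stem cell gene passed; without CD24low replicate 1, 1 Notch gene; without CD24low replicate 3, 2 stem cell and 2 ERK genes.

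Proliferation and stress lists did not pass camera in the main test, and some did under other settings. None of 24 DNA replication genes (median 0.01, camera adjusted p = 0.97), 24 mitosis genes (0.0040, 0.93), 14 replication histone genes (0.09, 0.22) or 21 cholesterol synthesis genes (-0.10, 0.15) passed limma's test over the list alone. Their smallest p-values belonged to TYMS (0.55), which makes thymidylate, the mitotic kinesin KIF20A (0.27), the histone HIST1H2BD (0.22; 0.11 without CD24high replicate 3, 0.36 without CD24low replicate 2) and the sterol carrier STARD4 (-0.37; -0.11 without CD24high replicate 1, -0.57 without CD24high replicate 3). Without CD24low replicate 2, camera called the DNA replication list (median 0.14, adjusted p = 0.0020) and the histone list (0.28, 1.2e-06), and with the rRNA covariate the histone list (0.20, 0.0022); without CD24low replicate 3 their medians were -0.11 and -0.06. The cholesterol list passed without CD24low replicate 1 (-0.20, 0.0060), without CD24low replicate 3 (-0.18, 0.042) and without both libraries numbered 3 (-0.23, 0.014). Its median was 0.04 without CD24low replicate 2 (0.42). These calls used the preset correlation of 0.01. In the main fit the estimated correlations of the DNA replication, histone and cholesterol lists were 0.65, 0.87 and 0.65. With them camera's adjusted p was 0.98 for each list. Of 20 NF-kB genes 17 were tested and 0 passed (median 0.12, camera adjusted p = 0.97), with IL1A at -1.11. However, 10 NF-kB genes passed without CD24low replicate 3 and 7 with the replicate block. With DESeq2 over the list alone 5 passed, and without CD24high replicate 3, 1. The NF-kB median was -0.04 without CD24high replicate 2 and 0.31 without CD24high replicate 1. Of 20 immediate early and heat shock genes 0 passed (median 0.02, camera adjusted p = 0.93), with ATF3 at -0.50, and 1 passed without CD24low replicate 3. The median of that list was 0.15 without CD24low replicate 3 and -0.02 without CD24high replicate 1. Without CD24high replicate 3, 1 DNA replication gene passed. In the interferon list IFI6 rose (7.99 ± 0.96 and 45.8 ± 28.5, difference 2.22) and 18 of 19 did not pass (median 0.02, camera adjusted p = 0.93). The interferon count of 1 was 2 without CD24low replicate 1 and 3 without CD24low replicate 2. The interferon median ran from -0.09 without CD24high replicate 2 to 0.05 without CD24low replicate 1. Of 13 mitochondrially encoded mRNAs MT-ND6 fell (388 ± 17.2 and 221 ± 47.2, difference -0.83) and 12 did not pass (median -0.17, camera adjusted p = 0.22), and without CD24high replicate 3 the count was 0, the median 0.21 and camera's adjusted p 0.085. The medians of that list were 0.01 and -0.72 within low and high rRNA share. That list had an estimated correlation of 0.81, with which camera's adjusted p was 0.98 in the main fit. It passed camera in opposite directions, with a median of -0.43 with the rRNA covariate (adjusted p = 1.5e-07), -0.38 without CD24high replicate 1 (0.0012) and -0.32 without CD24low replicate 1 (0.027), but 0.32 without both libraries numbered 3 (6.6e-05). Over all genes, limma called 0 members of these lists, and DESeq2 called 1 DNA replication gene (TYMS), 1 interferon gene and 1 mitochondrial gene.

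Markers of other cell types were mostly below the level tested. Of 13 leukocyte markers 3 were tested, and CSF1R, a macrophage growth factor receptor, fell (65.4 ± 3.80 and 37.2 ± 7.64, difference -0.82); that count of 1 was 0 without CD24high replicate 1 or CD24high replicate 3 and 2 without CD24low replicate 1 or CD24low replicate 3. Of 10 endothelial markers, PECAM1 alone was tested and did not pass (207 ± 164 and 233 ± 119 normalized counts). Of 14 fibroblast markers 4 were tested: DCN and TWIST2 rose, FAP fell and 1 did not pass over the list alone, and all 3 are also members of the matrix or mesenchymal lists. COL1A2 had 1 read and LUM 0 reads over the 6 libraries, and COL3A1 had means of 0.28 and 5.40 normalized counts. These 3 lists were counted by gene, and too few members were tested for camera; over all genes limma called 0 members, and DESeq2 called 1 fibroblast marker higher and 1 lower.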

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

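The fits with the rRNA covariate, with protein-coding genes alone and without both libraries numbered 3 were chosen after the results were seen. Limma's count of 0 genes (2164 at an unadjusted p below 0.05) stayed 0 with other pseudocounts, a higher filter, other scalings, no trend, the rRNA covariate, protein-coding genes alone and edgeR (2263 unadjusted). It became, in all, higher, lower and at least 2-fold: 164, 109, 55 and 139 with no filter; 402, 218, 184 and 217 with DESeq2; and 103, 64, 39 and 96 without both libraries numbered 3. The replicate number as a block gave 716, 347, 369 and 362 with limma and 705, 345, 360 and 365 with edgeR. Leaving out 1 library gave 0 to 366, 0 to 181, 0 to 185 and 0 to 288, with the highest values without CD24low replicate 3 and 0 without any other library. Of DESeq2's 402 genes, 147 were also called with no filter, 375 with limma's replicate block, 368 with edgeR's, 234 without CD24low replicate 3 and 74 without both libraries numbered 3. The log2 difference of CD24 passed the adjusted threshold at -2.55 with no filter (adjusted p = 0.0090), -2.55 with the replicate block in limma and -2.55 in edgeR, -2.40 with DESeq2 and -2.80 without both libraries numbered 3; over 21 alternatives its adjusted p ran from 2.1e-06 to 0.29, and with 1 library left out the difference ran from -3.10 (without CD24low replicate 3, the only such fit that passed, adjusted p = 0.0064) to -2.07. Fewer libraries or more genes are built into some of these settings; the cause was otherwise not tested. The libraries share only a number: correlations of same-numbered libraries were 0.27, 0.30 and 0.05 where 0.1 was needed in each, although 5 of 6 libraries correlated best with their own number, a hint from the data. The count of lists past camera was 7 to 14 with 1 library left out and 0 with an estimated correlation. The ribosomal protein median turned to -0.029 without both libraries numbered 3. Left-out libraries turned CBFB (-0.28 to 0.0041) and PECAM1 (-0.18 to 0.92), which were not called; the cause was not tested. The difference in the log2 ratio of RUNX2 to RUNX1 was 1.85 to 2.52 over 18 alternatives, and CD44 was not called in any of 21. Total scaling moved the median of all genes to -0.04. Of values for named genes under alternatives, 1240 kept their direction and side of the threshold, 280 newly passed it and 3 turned sign. Depth limits low counts most in CD24high replicate 3.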

Other observations

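The gene families and all tests of explanations in this part were chosen after the results were seen. Genes sharing a symbol stem were grouped into 403 families of 5 to 100 tested members, and 16 passed camera with a preset correlation, 0 with an estimated one (smallest adjusted p 0.997). All 5 tested IGFBP genes, which encode binding proteins of insulin-like growth factors, were higher in CD24low cells, with a median log2 difference of 1.54 (camera adjusted p = 3.5e-05). IGFBP4 had means of 3.88 and 43.1 normalized counts in CD24high and CD24low cells, IGFBP7 189 and 612, and IGFBP6 226 and 399. All 6 KLK genes, a cluster of secreted proteases on chromosome 19, were lower, with a median of -1.18 (camera adjusted p = 0.00012), KLK5 at 4382 and 1650 normalized counts. The KLK median was -0.12 within libraries of low rRNA share, where KLK9 was at 0.28, and -2.02 within those of high share; the IGFBP medians were 1.01 and 2.40, with IGFBP3 at -0.13 in the latter. Of 9 SERPINB protease inhibitor genes 8 were lower (median -1.10, camera adjusted p = 0.0011; -0.51 and -1.75 within low and high rRNA share), with SERPINB6 the exception. For each of these families the adjusted p was 0.997 with an estimated correlation.

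All 8 tested AKR genes, aldo-keto reductases, had a higher mean log2 value in CD24low cells (median 0.51, camera adjusted p = 0.0020; 0.35 and 0.76 within low and high rRNA share), with AKR1C1 at 605 and 984 normalized counts. Of 13 ALDH genes, aldehyde dehydrogenases, 11 were higher (median 0.43, camera adjusted p = 0.018), while ALDH1A3 was lower, at 2690 and 1581 normalized counts (-0.88, SE 0.34, limma adjusted p = 0.30; 0.13 and -1.65 within low and high rRNA share). The ALDH medians were 0.25 and 0.38 within low and high share, and for the AKR and ALDH families the adjusted p was 0.997 with an estimated correlation. The medians of these 5 families kept their sign under total scaling, quantile normalization and upper quartile centring. Adjusted over all genes by limma, 0 members of these families passed; DESeq2 called IGFBP2, IGFBP4, IGFBP6, KLK5, KLK6, SERPINB2, SERPINB7, SERPINB13, AKR1B1 and AKR1C1. The 13 PCDHA, 10 UGT and 12 NPIPB genes were all lower, but PCDHA genes, UGT1A genes and NPIPB genes share exons or near-identical copies, so their members are not independent. UGT8, on chromosome 4 and outside the UGT1A cluster, had 293 and 201 normalized counts (-0.56).

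CD24low replicate 3 lay between the other CD24low libraries and the CD24high libraries. On a scale from 0 (CD24high replicates 1 and 2) to 1 (CD24low replicates 1 and 2), its median position was 0.22 over 169 genes higher and 0.37 over 87 genes lower in CD24low cells. These genes were chosen in the libraries that set the scale, which pulls a library outside that choice inward. Treated the same way against the remaining CD24low libraries, CD24low replicate 1 lay at 0.53 (123 genes higher) and 0.87 (26 lower), and CD24low replicate 2 at 2.96 (38) and 1.07 (14). Uneven removal of rRNA, which the library shares with CD24high replicates 1 and 2, is argued against as the whole cause, because CD24high replicate 3, with a high rRNA share, stayed at -0.026 and -0.21 in the same genes. CD24high cells mixed into that sample might give such a place and cannot be told apart from a weaker shift of the cells: the positions differed by 0.14 (95% bootstrap interval 0.05 to 0.23), but by -0.18 in CD24high replicate 3, where no mixture is needed. A difference between cultures or sorts stays open, untested.

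The share of rRNA reads differed between libraries of the same group. Uneven depletion may be the source: RNA5-8SN2, a nuclear rRNA, was higher by 1.64 on the log2 scale in the 3 libraries of high share, beside 4.51 for MT-RNR1 and 3.46 for MT-RNR2. More mitochondrial RNA in those cells cannot be told apart for part of it, since the 13 mitochondrial mRNAs had a median difference of 0.65, with a range of 0.01 to 1.51. The sorted group is argued against as the whole cause, because 0 of 3 CD24low libraries lay outside the range of the CD24high libraries. High shares fell in 2 CD24low libraries and 1 CD24high library, so a part played by the group cannot be told apart.

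The mesenchymal list was higher in CD24low cells. The gate for low CD24 and high CD44 would not remove fibroblasts. Fibroblasts rich in COL1A2, COL3A1 and LUM are argued against in the CD24low samples. These genes are abundant in fibroblasts, and their summed rise was 0.025% of the rise of FN1. Only COL3A1 rose among them, with 1 read of COL1A2 and 0 of LUM in all 6 libraries. The genes were chosen after their values were seen, so fibroblasts that lack them stay open. Other fibroblast genes did rise: DCN had means of 160 and 1845 normalized counts, a rise of 1685 beside 19378 for FN1, and COL1A1 had 28.6 and 65.1. Uneven removal of rRNA is argued against as the whole cause, though weakly. The medians of all 19 tested members were 0.33 and 1.41 within libraries of low and of high rRNA share. Within low share, which rests on CD24low replicate 3 alone, 12 of 19 were positive. Within high share, which rests on CD24high replicate 3 alone, all 19 were. The median was 0.70 with the rRNA split as a covariate. That fit averages the low-share and high-share differences of each gene, so it adds no separate evidence. A difference in state between the sorted fractions stays open, untested.

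The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Genes past limma's adjusted p numbered 0 in the real split and at most 1 in the others, so all 10 splits reached the real value. At an unadjusted p below 0.05 the real split had 2164 genes and the highest other 1327, with DESeq2 402 and 92, and by list genes past the test over the list alone 82 and 31; only 1 split, the real one, reached each of these values. The same split gave 1327 and 92 genes and followed the rRNA share (CD24high replicates 1 and 2 with CD24low replicate 3), and with that share as a covariate limma called 0 genes at the adjusted p and 1786 at an unadjusted p below 0.05. For lists past camera, 4 splits reached the real 10, with a highest of 14.

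Along the chromosomes, medians of 265 windows of 10 Mb with at least 20 tested genes ran from -0.30 to 0.21, where 100 shuffles of the genes gave -0.22 to 0.21. Medians of 4 windows lay below all shuffles, on chromosomes 9 (2 windows), 18 and 19, and 1 lay above them, on chromosome 20. All 11 windows of chromosome 9 and all 8 of chromosome 18 were below 0. Windows below 0 were common elsewhere too, with 13 of 14 on chromosome 4 and 11 of 13 on chromosome 8, against 0 of 5 on chromosome 22. The median of the windows was -0.13 on chromosome 9, -0.11 on chromosome 4 and -0.08 on chromosome 18. A gained or lost chromosome copy in cells of one group cannot be told apart from a difference in regulation. The bound of 0.4 set for a copy in most cells was assumed, and the median farthest from 0 was -0.30. That median was of the chromosome 18 window from 60 Mb, with 26 genes. The window holds tested SERPINB genes, all lower, from -1.96 (SERPINB13) to -0.25 (SERPINB8), so that family contributes to its median. On chromosome 19 the window below all shuffles was the only 1 of 6 below 0.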
